A study of Mus musculus with 19 samples.

How the data were processed

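Gene expression was measured in mouse CD4+ T cells on 19 Affymetrix arrays, 1 array per sorted sample, each hybridised with biotin-labelled cDNA per the labels' protocols. Per a protocol text that the labels give for all samples, OT-II cells, CD4+ T cells with a transgenic receptor for an ovalbumin peptide, carried a BCL6-YFP reporter allele and were transferred into mice that were then immunized under the skin with hapten-coupled ovalbumin in complete Freund's adjuvant. Cells were sorted from draining lymph nodes at day 7 or day 10, and naive CD4+ cells from the spleen of unimmunized mice. The text may not describe naive cells or Bcl6+/+ cells, which lack the reporter allele. The deposited values are log2 expression values per probe set; per the submitters' processing notes the authors used GCRMA, a background correction and summary of the probes of each probe set, whose version and settings are not given in the sources used here. Array medians ran from 2.40 to 2.99 and 40.9% to 46.6% of probe sets reached log2 4 on an array. The number of arrays limits the precision.

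The columns did not share 1 distribution. Arrays whose sorted values differed by under 0.06 log2 on average were taken as normalized together, which gave 7 sets (differences at most 0.0482 within and at least 0.0667 between sets). YFP-positive, YFP-negative and CXCR5lo PD-1lo replicates 1, 2 and 3 formed sets 1, 2 and 3 by replicate number. Set 4 held YFP-positive and YFP-negative replicate 4 with naive replicate 1. Set 5 held Bcl6yfp/+ replicate 1 with naive replicate 2, set 6 Bcl6yfp/+ and Bcl6+/+ replicates 2 and 3, and set 7 Bcl6+/+ replicate 1 alone. Changes between groups are therefore also given with the set as a block and within each set that holds both groups.

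Probe sets were named through the platform annotation that GEO provides, matched by Entrez identifier to the RefSeq gene table of assembly GRCm38.p6. Of 45101 probe sets, 34945 carried 1 symbol, 932 several and 9160 none, and 64 were controls; 34741 matched by identifier and 0 symbols were updated. The annotation names no probe set for some genes, which are not reported here. A probe set was kept where it reached log2 4 on at least 2 arrays, which left 22327. Each gene was represented by its probe set with the highest mean over all arrays, giving 9930 genes. A log2 value near 2 is the floor of the GCRMA scale, so a fold change against a group at that level depends on the floor.

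Group means were fitted to all 19 arrays in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), so that all groups shared 1 estimate of the spread. The day effect was fitted as a term added to the groups, estimated from the 3 groups that hold both days. P-values were adjusted by Benjamini-Hochberg within a comparison over the 9930 genes, and a gene was called at an adjusted p under 0.05; all adjusted p-values below come from limma. Errors of fold changes are standard errors (SE) of the fit, and errors of levels are standard deviations (SD). The labels do not say that arrays of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

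The comparisons, 26 gene lists, alternatives and the rule for genes named in the text were written down before the data were examined. The lists were Tfh genes, Th1 and cytotoxic effector genes, Th17 genes, Th2 genes, regulatory T cell genes, naive and memory T cell genes, genes reported to be repressed by BCL6, helper lineage transcription factors, chemokine receptors and homing molecules, cytokine receptors, co-stimulatory and inhibitory receptors, cell cycle genes, immediate early and TCR response genes, heat shock genes, interferon-induced genes, glycolysis genes, oxidative phosphorylation genes, cholesterol synthesis genes, apoptosis genes, T cell identity genes, and markers of B cells, of germinal centre B and plasma cells, of myeloid and dendritic cells, of CD8 T and NK cells, of erythroid cells and platelets, and of stromal and endothelial cells. Lists overlap, so that Klf2 and S1pr1 stand in several. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Calls are counted over all genes and adjusted over the list alone. Of the marker lists, naive T cells themselves had 1 of 17 B cell, 1 of 7 germinal centre B and plasma cell, 2 of 19 myeloid, 1 of 7 CD8 T and NK, 1 of 11 stromal and 0 of 6 erythroid genes at log2 8 or more. No erythroid gene passed the filter, and of the stromal list only Pecam1 did.

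Named genes are, among called genes whose groups do not overlap, the 10 highest and 10 lowest log2 fold changes between the YFP-positive, YFP-negative and CXCR5lo PD-1lo groups and between the Bcl6 genotypes, and 5 and 5 elsewhere (for the day effect, genes that moved the same way in each of the 3 groups). Symbols of undescribed genes (Gm or LOC with digits, names ending in Rik, clone names) were skipped. To these come up to 4 called members of each list with the largest change, or the 2 with the smallest p where none was called, and Bcl6, Cxcr5, Pdcd1 and Cd44. These last genes, of the sorts and the reporter, check the labels and are no findings.

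The fit was tested on simulated values for the same 9930 genes with 200 changed genes. For YFP-positive against YFP-negative it recovered 38.8% of changes of log2 1, 88.1% of log2 2 and 92.4% of log2 3, with 3.95% false calls; with simulated set effects of the fitted size these shares fell to 14.9%, 71.6% and 80.3%. For YFP-positive against CXCR5lo PD-1lo the recovered shares were 26.9%, 80.6% and 95.5% without set effects and 8.96%, 71.6% and 92.4% with them. For the Bcl6 genotypes they were 23.9%, 65.7% and 84.8% without and 8.96%, 55.2% and 84.8% with them. The fit with replicate number as a block made 9.09% false calls between the genotypes with set effects. These effects were taken from the same data, so the simulation does not test whether they cause a shift.

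Replicate numbers in the titles are shared between groups. Deviations from the group means were correlated between arrays of the same number at r = 0.45 to 0.868 for YFP-positive and YFP-negative (other numbers -0.651 to 0.251), 0.391 to 0.684 for YFP-positive and CXCR5lo PD-1lo (-0.617 to 0.381), 0.267 to 0.387 for YFP-negative and CXCR5lo PD-1lo (-0.371 to 0.388) and 0.572 to 0.64 for Bcl6yfp/+ and Bcl6+/+ (-0.633 to 0.555), across genes, which are not independent replicates. Every same-numbered pair was above 0.1, so the numbers were taken to pair the arrays, and a fit with the number as a block was made beside the fit without it. Other numbers reached 0.251, 0.381, 0.388 and 0.555, so this cut-off does not separate pairs from other arrays. Same-numbered YFP-positive, YFP-negative and CXCR5lo PD-1lo arrays also share a normalization set, so pairing and shared normalization cannot be told apart. Replicates 1 of the Bcl6 genotypes (r = 0.64) are in different sets, but both had high 3' to 5' differences of control probe sets. In set 1 the YFP-positive array is from day 7 and the YFP-negative array from day 10, and Xist was 13.77 and 1.97 on them. A wrong day or replicate label could not be excluded there, which limits the fits with the replicate block.

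Alternatives were the filter, other probe sets or their mean, all probe sets, quantile normalization of all arrays, limma's trend and robust options, arrayWeights, the arrays of the compared groups alone, the replicate number, extraction label or day as a block or covariate, day 7 arrays alone, another list test (fry) and leaving out each array. After the data were examined, further ones were added: the normalization set as a block, alone or with quantile normalization, the replicate number as a block for lists and named genes, blocks with only 11 arrays or with replicate numbers 2 to 4, the fit without 3 arrays with high 3' to 5' differences of control probe sets, the day effect without genes of chromosomes X and Y, lists without YFP-negative replicate 1, CXCR5lo PD-1lo replicate 1 or Bcl6yfp/+ replicate 1, and the Bcl6+/+ day effect against the day 7 arrays of both genotypes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.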

Results

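Sorted CD4+ T cells of 6 groups were compared. Immunized mice gave CXCR5hi PD-1hi cells that were YFP-positive (n = 4) or YFP-negative (n = 4) for the BCL6 reporter, CXCR5lo PD-1lo cells (n = 3), and CXCR5hi PD-1hi cells of Bcl6yfp/+ (n = 3) and Bcl6+/+ (n = 3) genotype. Naive CD4+ cells (n = 2) came from the spleen of unimmunized mice, and the cells of the other groups from lymph nodes. CXCR5 draws T cells to B cell follicles, PD-1 (gene Pdcd1) is an inhibitory receptor, and BCL6 is a transcriptional repressor needed by follicular helper T (Tfh) cells. The number of arrays limits the precision.

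YFP-positive cells (n = 4) differed from YFP-negative cells (n = 4) in 12 genes, among them Klf2, S1pr1 and Scml4. As 3 of 35 splits of these arrays, the real one included, gave as many genes, chance could not be excluded for the count. YFP-positive replicate 4 and YFP-negative replicates 1 and 4 are from day 10 and carry Y-linked transcripts. The groups are therefore not balanced in day or in sex-linked transcripts. Klf2, a transcription factor that keeps T cells quiescent and recirculating, fell 12.8-fold (log2 -3.67, SE 0.46, adjusted p = 0.0019, limma; lower in 4 of 4 YFP-positive arrays than in every YFP-negative array). S1pr1, the receptor that guides lymphocytes out of lymph nodes, fell 10.1-fold (log2 -3.33, SE 0.50, adjusted p = 0.012). Scml4, a Polycomb-related gene, fell 29.1-fold (log2 -4.86, SE 0.56, adjusted p = 0.0019). Bcl6 itself was high in both groups, with log2 means of 14.3 in YFP-positive and 13.9 in YFP-negative cells (log2 difference 0.36, SE 0.21, adjusted p = 0.88). The sorting markers did not pass either: Cxcr5 differed by log2 0.17 (SE 0.26), Pdcd1 by 0.04 (SE 0.28) and the activation marker Cd44 by -0.21 (SE 0.25).

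In all, 12 of 9930 genes passed between YFP-positive and YFP-negative cells, 4 higher and 8 lower (786 at an unadjusted p under 0.05). This balance was not stable, with 265 higher and 42 lower without YFP-positive replicate 4. With the replicate number as a block, which compares arrays of the same number, 74 passed, 31 higher and 43 lower. All 12 passed in both fits. With the normalization set as a block 1541 passed (828 higher, 713 lower). For these groups the sets match the replicate numbers, so both blocks compare the same pairs and give the same fold changes. The counts differ in the spread alone, which other groups help to set, so 1541 does not measure an effect of normalization. Of all genes, 386 (3.89%) had groups that did not overlap, where chance gives 2.86%. The other named genes that rose were the cilium gene Tmem107 (log2 3.52, SE 0.61, adjusted p = 0.027), the membrane receptor Dcbld2 (2.60, SE 0.33, adjusted p = 0.0019, but -0.11 at another probe set), Spata24 (2.13, SE 0.40, adjusted p = 0.049) and the kinesin Kifc5b (1.94, SE 0.33, adjusted p = 0.026). The others that fell were the sodium channel Scn8a (log2 -3.71, adjusted p = 0.033), the interferon-inducible Ifi213 (-1.53, adjusted p = 0.016), the sugar phosphate enzyme Pgm2l1 (-1.51, adjusted p = 0.016) and the phosphatase Acpp (-1.36, adjusted p = 0.018). Of 6 other probe sets of the 11 called genes named here 5 went the same way and 0 passed. Within normalization sets 1 to 4, Klf2 differed by -3.56, -3.18, -4.10 and -3.86, S1pr1 by -2.32, -3.78, -4.03 and -3.19, and Scml4 by -6.17, -4.38, -4.35 and -4.55. Of the named genes, 11 of 11 kept their direction. For genes named because their groups did not overlap this was fixed in advance, so it does not test the normalization. Leaving out each array in turn, Klf2 ran from -4.09 to -3.19, Scml4 from -5.12 to -4.36 and Dcbld2 from 2.37 to 2.86. These 3 passed in every run, and the other 8 called genes named each lost their call in at least 1. S1pr1 lost it only without YFP-negative replicate 2 (adjusted p = 0.0527), while Tmem107, Spata24, Kifc5b, Scn8a and Acpp kept it in 2 of 8 runs, Pgm2l1 in 4 and Ifi213 in 5.

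**Figure D1:**
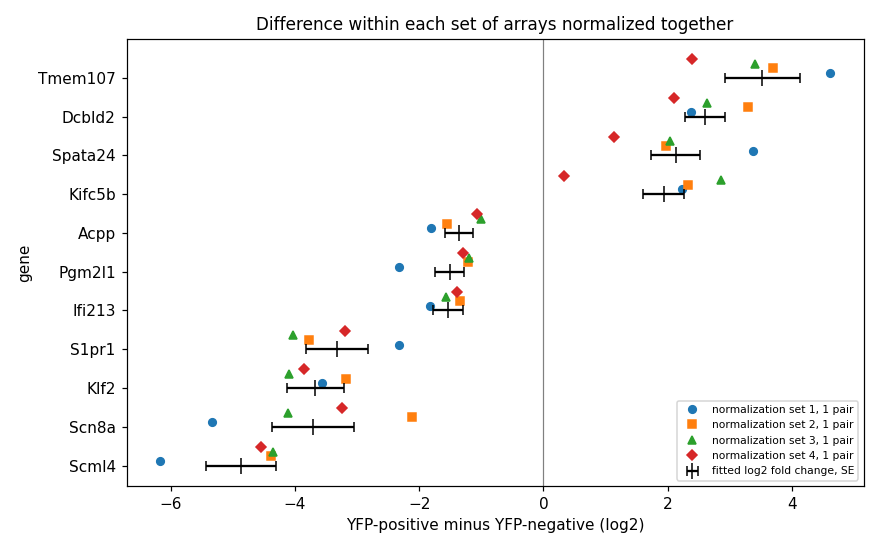
Difference between YFP-positive and YFP-negative cells (log2, x axis) of 11 named genes (y axis) within normalization sets 1 to 4, 1 pair of arrays per point, beside the fitted log2 fold change with its SE as bars. Klf2 ran from -4.10 to -3.18 within the sets and was -3.67 in the fit.

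Cell cycle genes, which drive DNA synthesis and mitosis, were higher in YFP-positive cells in 41 of 41 members (median log2 2.78, camera adjusted p = 1.3e-37, adjusted p = 0.15 with an estimated correlation). Of them 0 passed over all genes in limma and 36 rose when adjusted over the list alone. With the set as a block 26 passed. Within sets 1 to 4 the list median was 4.38, 1.74, 2.06 and 2.88, and in set 1 the arrays also differ in day. The thymidylate synthase gene Tyms (log2 3.15, SE 0.68) had an adjusted p of 0.11, and of 0.023 with the replicate block. The kinesin Kif20a (2.85, SE 0.75) had an adjusted p of 0.18. Interferon-induced genes were lower in 18 of 20 (median -0.54, camera adjusted p = 2.1e-09, adjusted p = 0.15 with an estimated correlation; 0 passed over all genes, 5 fell over the list alone), led by the transcription factor Irf7 (-0.91, SE 0.21, adjusted p = 0.11). Naive and memory T cell genes were lower (median -0.29, camera adjusted p = 4.3e-07, adjusted p = 0.15 with an estimated correlation). Klf2 and S1pr1 passed over all genes and 4 fell over the list alone. Il7r, the receptor for a survival cytokine, was lower by log2 -2.72 (SE 0.67, adjusted p = 0.14, and 0.045 with the replicate block), and the cytotoxic granule protease Gzma by -3.59 (SE 0.80, adjusted p = 0.11, and 0.024 with the block).

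Glycolysis genes were higher in 13 of 13 (median 0.36, camera adjusted p = 1.5e-06, adjusted p = 0.22 with an estimated correlation; 4 rose over the list alone). Cholesterol synthesis genes were higher in 13 of 13 too (median 0.51, camera adjusted p = 3.2e-05, adjusted p = 0.39 with an estimated correlation). Genes reported to be repressed by BCL6 were lower (median -0.24, camera adjusted p = 0.00026, adjusted p = 0.34 with an estimated correlation; 3 fell over the list alone, among them Klf2 and S1pr1). Smaller shifts were called for cytokine receptors (median -0.21, camera adjusted p = 0.019, adjusted p = 0.39 with an estimated correlation), helper lineage transcription factors (-0.06, camera adjusted p = 0.049, adjusted p = 0.68 with an estimated correlation) and oxidative phosphorylation genes (0.20, camera adjusted p = 0.049, adjusted p = 0.73 with an estimated correlation). Without YFP-negative replicate 1 the last 2 had 0.059 each, and helper lineage factors had 0.0735 with the set as a block. Tfh genes were not called (median 0.05, camera adjusted p = 0.72), nor were Th1 and cytotoxic effector genes (-0.02; 0.097), chemokine receptors and homing molecules (-0.03; 0.058) or TCR response genes (-0.14; 0.056, and 0.036 with the replicate block). With the set as a block TCR response genes had a camera adjusted p of 0.0503, and of 0.545 with an estimated correlation. In the fit without blocks the camera adjusted p was 0.46 for Th17 genes, 0.89 for Th2 genes, 0.59 for regulatory T cell genes, 0.96 for co-stimulatory and inhibitory receptors, 0.53 for heat shock genes, 0.65 for apoptosis genes and 0.46 for T cell identity genes. For markers of other cells it was 0.5 (B cells), 0.1 (germinal centre B and plasma cells), 0.46 (myeloid cells) and 0.89 (CD8 T and NK cells). Of the endothelial markers only Pecam1 passed the filter (log2 -0.37, SE 0.29), and no erythroid gene did.

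**Figure D2:**
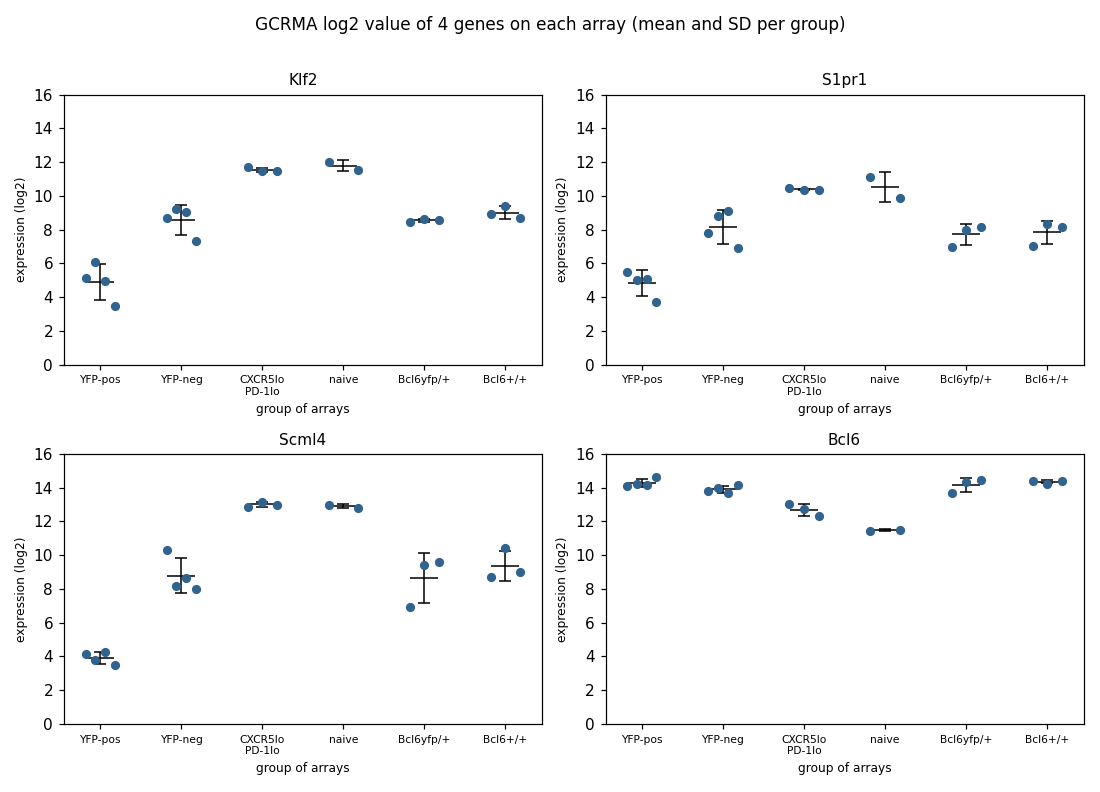
Level (log2, y axis) of Klf2, S1pr1, Scml4 and Bcl6 in the 6 groups (x axis), 1 point per array, with bars for the mean and SD of each group. The mean of Klf2 was 4.9 in YFP-positive and 8.6 in YFP-negative cells, and the mean of Bcl6 was 14.3 and 13.9.

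YFP-positive cells (n = 4) and CXCR5lo PD-1lo cells (n = 3) differed widely in helper and effector genes. Il4, a cytokine of Tfh and Th2 cells, rose 579-fold (log2 9.18, SE 0.53, adjusted p = 4.5e-09), and the secreted BMP antagonist Sostdc1 610-fold (9.25, SE 0.53, adjusted p = 4.5e-09). Both were near the floor in CXCR5lo PD-1lo cells (log2 means 4.0 and 3.3). Cxcr5 rose 13.9-fold (log2 3.79, SE 0.28, adjusted p = 1.1e-07), Pdcd1 9.82-fold (3.30, SE 0.30, adjusted p = 1.3e-06) and Bcl6 2.99-fold (1.58, SE 0.23, adjusted p = 0.00019). The groups were sorted on CXCR5 and PD-1 and by the BCL6 reporter, so these rises check the labels. All 3 genes also stand in the Tfh list. Nkg7, a cytotoxic granule gene, fell 498-fold to the floor (log2 -8.96, SE 0.20, adjusted p = 3.2e-14), and the protease Gzmb by log2 -8.19 (SE 0.24, adjusted p = 7.1e-13). Klf2 fell 101-fold (log2 -6.66, SE 0.49, adjusted p = 9.7e-08). In all 1049 genes passed (514 higher, 535 lower), 2068 with the replicate block and 4439 with the normalization set as a block. These blocks group the arrays of both cell types alike and give the same fold changes, so their counts differ in the spread alone. In 2274 genes (22.9%) the groups did not overlap, where chance gives 5.71%.

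Further genes with the largest rise in YFP-positive over CXCR5lo PD-1lo cells were Sccpdh (log2 9.01), H2-Q2 (7.70), Tnc (7.67), Coro2b (7.65), the inhibitory receptor Cd22 (7.33), the vitamin D receptor Vdr (7.26), Fam43a (6.82) and Padi4 (6.79). The largest falls were Ifitm1 (-9.15), Scml4 (-9.08), Dapl1 (-8.70), the chemokine receptor Ccr2 (-8.65), Tdrp (-8.53), Ctla2a (-8.52), the NK receptor gene Klrd1 (-8.48), Itgb3 (-8.29) and Igfbp4 (-8.25), with adjusted p at most 3.2e-07. Within sets 1 to 3, Sostdc1 differed by 8.07, 9.38 and 9.41, Il4 by 9.01, 8.96 and 9.41, Nkg7 by -9.15, -9.24 and -8.61, and Bcl6 by 1.05, 1.47 and 1.86. In all 68 of 68 named genes kept their direction, but this was fixed for those named because their groups did not overlap.

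Of 26 Tfh genes 14 rose and 1 fell in YFP-positive over CXCR5lo PD-1lo cells (median 1.24, camera adjusted p = 8.5e-14, adjusted p = 0.13 with an estimated correlation; 15 and 1 over the list alone), among them the transcription factors Ascl2 (log2 6.65, SE 1.37) and Cebpa (6.46, SE 0.78). Of 21 Th1 and cytotoxic effector genes 16 fell (17 over the list alone, camera adjusted p = 3.3e-19, and 0.0022 with an estimated correlation), among them Tbx21, the Th1 master regulator (log2 -6.21, SE 0.46, adjusted p = 1e-07). Naive and memory genes fell in 7 of 14 (10 over the list alone, camera adjusted p = 2.8e-10, and 0.025 with an estimated correlation), including Il7r (-6.64, SE 0.72) and the lymph node homing receptor Ccr7 (-5.68, SE 1.04). Cell cycle genes rose in 9 of 41 (23 over the list alone, 33 with the replicate block, camera adjusted p = 4.6e-13, adjusted p = 0.29 with an estimated correlation), led by the mitotic motor Cenpe (4.54, SE 1.30). CD8 T and NK markers fell in 3 of 4 (camera adjusted p = 1e-05, and 0.021 with an estimated correlation). The CXCR5lo PD-1lo arrays also carried Jchain, an antibody-cell gene, at 10.53, 7.906 and 7.724. It was 8.448 on YFP-positive replicate 1 and 2.208 to 3.063 on the other YFP-positive arrays. Whether RNA of other cells adds to the differences was not tested. Within sets 1 to 3 the median was 0.90, 1.40 and 1.34 for Tfh genes, -3.12, -4.67 and -3.11 for Th1 genes, and 1.19, 3.35 and 5.03 for cell cycle genes. With the set as a block camera gave 9.9e-08, 5.8e-08 and 5.8e-08 for these lists, but 0.165, 0.165 and 0.553 with an estimated correlation. Naive and memory genes (0.165) and CD8 T and NK markers (0.294) lost their call in that fit too.

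Camera also called genes reported to be repressed by BCL6 (9 fell, adjusted p = 2e-08, adjusted p = 0.075 with an estimated correlation), interferon-induced genes (10 fell; 1.1e-05, adjusted p = 0.18 with an estimated correlation) and chemokine receptors (9 fell, 1 rose; 3e-05, adjusted p = 0.18 with an estimated correlation). It called glycolysis genes (4 rose; 0.00085, adjusted p = 0.28 with an estimated correlation), TCR response genes (4 fell, 9 with the replicate block; 0.0031, adjusted p = 0.18 with an estimated correlation), co-stimulatory and inhibitory receptors (6 rose, 3 fell; 0.0033, adjusted p = 0.4 with an estimated correlation) and cytokine receptors (6 fell, 2 rose; 0.0035, adjusted p = 0.19 with an estimated correlation). Cholesterol synthesis genes had a camera adjusted p of 0.2, and of 0.02 with the replicate block.

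YFP-negative cells (n = 4) were compared with the same 3 CXCR5lo PD-1lo arrays, so this comparison is not independent of the one before. Sostdc1 rose 559-fold (log2 9.13, SE 0.53, adjusted p = 5.5e-09) and Il4 476-fold (8.90, SE 0.53, adjusted p = 6.6e-09). Cxcr5 rose 12.3-fold (log2 3.62, SE 0.28, adjusted p = 1.9e-07), Pdcd1 9.54-fold (3.25, SE 0.30, adjusted p = 1.7e-06) and Bcl6 2.33-fold (1.22, SE 0.23, adjusted p = 0.0025). The rises of Cxcr5 and Pdcd1 again follow from the sort. Nkg7 fell 467-fold (log2 -8.87, SE 0.20, adjusted p = 3.8e-14) and Tbx21 62.7-fold (-5.97, SE 0.46, adjusted p = 1.6e-07). In all 648 genes passed (311 higher, 337 lower), 1114 with the replicate block and 3026 with the set as a block. The fold changes are again the same with both blocks, so their counts differ in the spread alone. In 1852 genes (18.7%) the groups did not overlap, where chance gives 5.71%.

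The other largest rises in YFP-negative over CXCR5lo PD-1lo cells were Sccpdh (log2 8.24), H2-Q2 (7.74), Tnc (7.60), Coro2b (7.44), Asb2 (6.88), Fam43a (6.77), Vdr (6.77) and Scn11a (6.65), and the other largest falls Ifitm1 (-9.15), Dapl1 (-8.91), Ctla2a (-8.68), Itgb3 (-8.59), Igfbp4 (-8.30), Ccr2 (-8.20), Klrd1 (-8.18), Gzmb (-8.18) and Tdrp (-8.16). Within sets 1 to 3, Sostdc1 differed by 9.49, 8.26 and 8.82 and Il4 by 8.88, 8.54 and 9.23. In all 60 of 60 named genes kept their direction, which was again fixed for those named because their groups did not overlap. Of 26 Tfh genes 14 rose and 1 fell (camera adjusted p = 1.5e-18, adjusted p = 0.066 with an estimated correlation), and 15 of 21 Th1 genes fell (5.8e-21, and 0.0015 with an estimated correlation). Naive and memory genes fell in 7 of 14 (2.6e-07, adjusted p = 0.066 with an estimated correlation), genes reported to be repressed by BCL6 in 8 of 13 (1.8e-07, adjusted p = 0.066 with an estimated correlation) and CD8 T and NK markers in 3 of 4 (5.3e-07, and 0.008 with an estimated correlation). Th1 genes had 0.113 and CD8 T and NK markers 0.229 with the set as a block and an estimated correlation. Cell cycle genes were not called (0 of 41 over all genes and 0 over the list alone in limma; median -0.11, camera adjusted p = 0.93), and their median was -2.74, 1.30 and 2.75 within sets 1, 2 and 3. Without CXCR5lo PD-1lo replicate 1 the list was called higher (median 0.83, camera adjusted p = 0.00874, range over all alternatives 0.00441 to 0.986), and so it was with day as a covariate (0.75; 0.00441). All CXCR5lo PD-1lo arrays are from day 7, while the YFP-negative arrays with list means of 8.03 and 6.98 are from day 10 and those with 9.99 and 10.3 from day 7. Camera called chemokine receptors (11 fell, 1 rose; 2e-05, adjusted p = 0.2 with an estimated correlation), co-stimulatory receptors (5 rose, 2 fell; 0.0006, adjusted p = 0.39 with an estimated correlation), regulatory T cell genes (3 fell, 1 rose; 0.015, and 0.065 with the replicate block, adjusted p = 0.066 with an estimated correlation) and cytokine receptors (4 fell, 1 rose; 0.041, adjusted p = 0.39 with an estimated correlation). Regulatory T cell genes had 0.252 and cytokine receptors 0.111 with the set as a block. TCR response genes had 0.05, and 0.0016 with the replicate block. With the set as a block camera gave them 0.00989, but 0.431 with an estimated correlation.

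**Figure D3:**
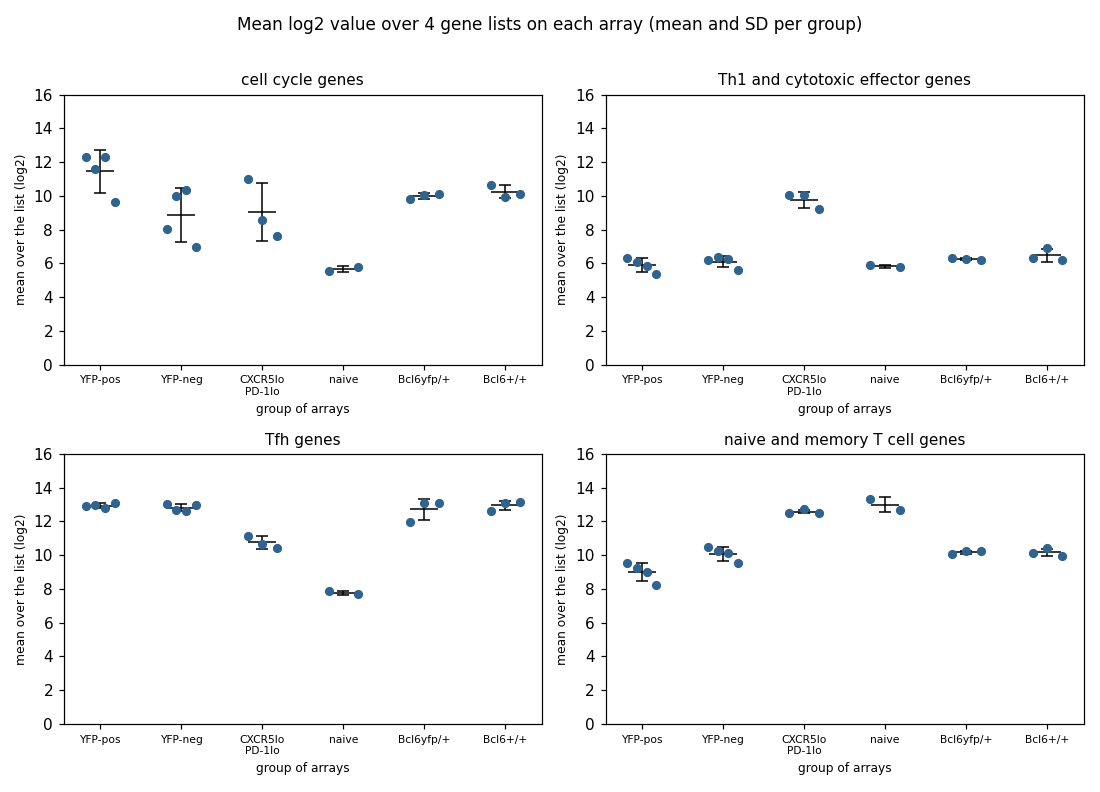
Mean log2 level (y axis) over the cell cycle, Th1 and cytotoxic effector, Tfh, and naive and memory lists in the 6 groups (x axis), 1 point per array, with bars for the mean and SD of each group. The cell cycle list did not pass between YFP-negative and CXCR5lo PD-1lo cells (camera adjusted p = 0.93).

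Against naive cells (n = 2), Cxcr5, Bcl6, Il21 and Tox2 rose in all 4 comparisons, which share the same naive arrays. Cxcr5 is a gene of the sort, so its rise in CXCR5hi cells checks the labels. Naive cells came from spleen and the others from lymph nodes, so tissue and immunization cannot be told apart in any of these comparisons. Relative to naive cells Cxcr5 rose by log2 11.55 (SE 0.32, adjusted p = 4.3e-13) in YFP-positive cells, 11.38 (SE 0.32, adjusted p = 5.4e-13) in YFP-negative cells, 7.76 (SE 0.34, adjusted p = 1.2e-10) in CXCR5lo PD-1lo cells and 11.32 (SE 0.30, adjusted p = 1.7e-13) in CXCR5hi PD-1hi cells of both genotypes. Bcl6 rose 6.89-fold, 5.38-fold, 2.31-fold and 6.82-fold in that order (adjusted p at most 0.0083). Il21, a cytokine that acts on B cells, rose by log2 11.16, 10.97, 7.22 and 11.32, and the transcription factor Tox2 by 11.25, 11.30, 9.55 and 11.53. The cytotoxic gene Nkg7 rose in CXCR5lo PD-1lo cells (log2 8.76, SE 0.24, adjusted p = 8e-13), as did S100a4 (11.31, SE 0.58, adjusted p = 8.9e-10). The quiescence gene Klf2 fell by log2 -6.90 (SE 0.56, adjusted p = 9.9e-08) in YFP-positive cells. The median of all genes was shifted by 0.394, 0.376, 0.461 and 0.504 in these comparisons, and by -0.0759, -0.0833, -0.0797 and 0.0721 after quantile normalization of all arrays, so list medians are given relative to it. Naive replicate 2, whose Gapdh control probe sets differed by 1.26 log2 between the 3' and 5' ends, is 1 of the 2 naive arrays, and without it the shifts were 0.256, 0.244, 0.34 and 0.382.

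In YFP-positive over naive cells 2863 genes passed (2222 higher, 641 lower, 77.6% higher, but 46.1% after quantile normalization), and 4663 with the set as a block. The share that rose was 78% in YFP-negative cells (2098 genes, 1637 higher, 461 lower), 45.1% after quantile normalization, and 4131 genes passed with the set as a block. It was 86.8% in CXCR5lo PD-1lo cells (1185 genes, 1028 higher, 157 lower), 46.3% after quantile normalization, and 2319 passed with the set as a block. It was 82.8% in cells of both genotypes (3410 genes, 2822 higher, 588 lower), 59.3% after quantile normalization, and 2451 passed with the set as a block. Genes with groups that did not overlap were 4978 (50.1%), 4631 (46.6%), 5382 (54.2%) and 3209 (32.3%), where chance gives 13.3%, 13.3%, 20% and 7.14%. Other top rises were Cebpa and Il1r1 in YFP-positive (11.60 and 11.03), YFP-negative (11.08 and 11.17) and both-genotype cells (11.16 and 10.88), and S100a6 (10.67), Gcnt1 (10.07) and Bhlhe40 (9.98) in CXCR5lo PD-1lo cells. The top falls were Igfbp4 (-10.42, -10.47 and -9.53), Tdrp (-9.94, -9.57 and -8.79), Itgb3 (-9.68, -9.98 and -8.74) and Pdlim4 (-9.64, -9.65 and -9.65) in these 3 comparisons. Dapl1 fell in YFP-positive and YFP-negative cells (-9.53 and -9.74) and Ctsw in both-genotype cells (-9.33). In CXCR5lo PD-1lo cells the top falls were Pdlim4 (-6.44), Myo6 (-5.88), Dapk1 (-5.57), Dntt (-5.56) and Gabrr2 (-5.41). Several of these start from the floor in 1 of the groups. The set that holds YFP-positive, YFP-negative and naive arrays gave a Cxcr5 difference of 11.79 for YFP-positive cells, and the set with Bcl6yfp/+ replicate 1 and naive replicate 2 gave 10.53. CXCR5lo PD-1lo and naive arrays share no set.

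Tfh genes rose in 25 of 26 in YFP-positive, YFP-negative and both-genotype cells and in 19 of 26 in CXCR5lo PD-1lo cells over naive cells (relative medians 3.48, 3.45, 3.25 and 1.53, camera adjusted p = 3.4e-19, 2.7e-23, 1.5e-18 and 2.9e-16, adjusted p = 0.13, 0.07, 0.14 and 0.067 with an estimated correlation). With the set as a block and an estimated correlation camera gave 0.0645, 0.0459, 0.0226 and 0.0273 in that order. Naive and memory genes fell in 8 of 14, 8 of 14, 8 of 14 and 1 of 14 (camera adjusted p = 1.7e-12, 3.1e-10, 3e-10 and 0.00038, adjusted p = 0.034, 0.07, 0.068 and 0.2 with an estimated correlation). With the set as a block they fell in 12, 12, 10 and 10 of 14 (camera adjusted p = 4.13e-07, 1.94e-06, 9.31e-06 and 2.57e-05, adjusted p = 0.125, 0.117, 0.128 and 0.0831 with an estimated correlation, so the call in YFP-positive cells was lost there). Cell cycle genes rose in 36, 21, 33 and 18 of 41 (camera adjusted p = 1.7e-12, 0.00016, 3.4e-07 and 5e-06, adjusted p = 0.41, 0.67, 0.53 and 0.46 with an estimated correlation), the proliferation marker Mki67 by log2 9.40, 7.67, 7.91 and 7.49. With the set as a block the cell cycle list was not called in YFP-negative (4 rose, 1 fell, adjusted p = 0.27) or CXCR5lo PD-1lo cells (2 rose, adjusted p = 0.58). Th1 and cytotoxic effector genes rose in 13 of 21 in CXCR5lo PD-1lo cells (camera adjusted p = 1.6e-10, and 0.018 with an estimated correlation, but 0.15 with that and the set as a block) and were not called in the other 3 comparisons (0.15, 0.32 and 0.18). Whether list shifts differ between groups was not tested.

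Glycolysis genes were called higher in YFP-positive, YFP-negative, both-genotype and CXCR5lo PD-1lo cells over naive cells (camera adjusted p = 0.0011, 0.027, 0.0054 and 0.031, adjusted p = 0.37, 0.59, 0.47 and 0.46 with an estimated correlation). Hk2, which starts glycolysis, rose by log2 6.14, 3.74, 4.96 and 6.07. Helper lineage transcription factors were called higher too (0.041, 0.0023, 0.0042 and 4e-06, adjusted p = 0.65, 0.54, 0.53 and 0.22 with an estimated correlation), and Maf among them rose by 7.08, 7.02, 7.14 and 6.42. Genes reported to be repressed by BCL6 were called lower in the first 3 of these groups (0.0015, 0.012 and 0.0086, adjusted p = 0.37, 0.54 and 0.47 with an estimated correlation), while Ccr6 of that list rose by 7.32, 5.69 and 6.72. The set block left only the call in YFP-positive cells (0.0323, 0.0566 and 0.326). TCR response genes were called higher in YFP-negative (0.012, adjusted p = 0.24 with an estimated correlation) and both-genotype cells (0.0086, adjusted p = 0.28 with an estimated correlation). With the set as a block camera called them in YFP-positive cells too (0.00375, adjusted p = 0.37 with an estimated correlation). CD8 T and NK markers were called lower in the same groups (0.029 and 0.0086, adjusted p = 0.24 and 0.17 with an estimated correlation), where Klrd1 fell by log2 -8.10 and -7.88, but not with the set as a block (0.162 and 0.509). Th2 genes were called higher in YFP-negative (0.033, adjusted p = 0.24 with an estimated correlation) and CXCR5lo PD-1lo cells (0.031, adjusted p = 0.2 with an estimated correlation), and cholesterol synthesis genes lower relative to the shift (0.016 and 0.026, adjusted p = 0.59 and 0.46 with an estimated correlation). Only 3 of the 9 Th2 genes on the array passed the filter, and Il4 of that list also stands in the Tfh list. The set block also gave Th2 calls by camera in YFP-positive and both-genotype cells (0.0236 and 0.0247, adjusted p = 0.228 and 0.232 with an estimated correlation). In CXCR5lo PD-1lo cells chemokine receptors (0.0041, adjusted p = 0.36 with an estimated correlation) and interferon-induced genes (0.031, adjusted p = 0.46 with an estimated correlation) were called higher. With the set as a block chemokine receptors were not called there (0.171), and interferon-induced genes were called higher in both-genotype cells too (11 rose; 0.000878, adjusted p = 0.633 with an estimated correlation).

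Th17 genes were called in all 4 comparisons with naive cells (6, 6, 6 and 7 of 7 rose, camera adjusted p = 8.4e-05, 0.00012, 0.00038 and 1.9e-09, adjusted p = 0.14, 0.14, 0.17 and 0.019 with an estimated correlation in YFP-positive, YFP-negative, both-genotype and CXCR5lo PD-1lo cells), as were co-stimulatory and inhibitory receptors (2.2e-09, 9e-12, 9.5e-10 and 7.4e-14, adjusted p = 0.14, 0.093, 0.17 and 0.034 with an estimated correlation). Of the receptors, Lag3 rose by log2 9.47, 9.10, 9.63 and 7.95. In CXCR5lo PD-1lo cells regulatory T cell genes (7 of 12 rose; 3.4e-05, and 0.018 with an estimated correlation) and TCR response genes (14 of 21 rose; 3e-06, and 0.03 with an estimated correlation) were called too. In CXCR5lo PD-1lo cells these lists, Th17 genes and the receptors lost their calls with the set as a block and an estimated correlation (0.0544, 0.0825, 0.0831 and 0.0825). Irf4, a transcription factor induced by TCR signals, rose by log2 4.99, 5.02, 5.26 and 6.17. The adhesion receptor and B cell list gene Cd22 rose by log2 8.98, 8.25 and 8.32 in YFP-positive, YFP-negative and both-genotype cells. Ighm was lower at its highest probe set (-0.70, -0.76 and -0.75), but other probe sets of the gene went the other way, so it has no single direction here. At its probe set with the widest range naive arrays read 2.121 and 2.204. YFP-positive replicate 1 read 12.05 there and the other YFP-positive arrays 2.068 to 2.421. YFP-negative replicate 1 read 14.96 and the others 2.092 to 3.983. The rise in these groups therefore rests on replicate 1 at that probe set.

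Bcl6yfp/+ (n = 3) and Bcl6+/+ (n = 3) CXCR5hi PD-1hi cells were not told apart by any gene of the sort. All Bcl6yfp/+ arrays are from day 7, while Bcl6+/+ replicates 1 and 2 are from day 10 and replicate 3 from day 7. Genotype and day can therefore not be fully told apart here. Bcl6 differed by log2 -0.20 (SE 0.24, adjusted p = 0.87), Cxcr5 by -0.25 (SE 0.30, adjusted p = 0.87) and Pdcd1 by -0.11 (SE 0.32, adjusted p = 0.93). The integrin Itga4 had -1.50 (SE 0.37, adjusted p = 0.87) and the orphan receptor Gpr83 -2.03 (SE 0.67, adjusted p = 0.87). In limma 0 of 9930 genes passed (287 at an unadjusted p under 0.05, smallest adjusted p = 0.432), 0 with the replicate block and 4 with the set as a block. In 455 genes (4.58%) the groups did not overlap, where chance gives 10%. The median of all genes was shifted by -0.262 (-0.0517 after quantile normalization), so a list can be called higher by camera while its own median is negative. Without Bcl6yfp/+ replicate 1 the shift was -0.00111, so it rests on 1 array, whose control probe sets differed between the 3' and 5' ends by 1.41 (Actb) and 1.02 (Gapdh) log2. These differences were larger on Bcl6+/+ replicate 1 (1.56 and 2.34), whose 75th percentile of log2 values was 9.25. On Bcl6yfp/+ replicate 1 that percentile was 8.56, as on naive replicate 2 of the same normalization set. What caused the shift was not tested.

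Camera called 10 lists between the Bcl6 genotypes, all higher relative to the shift, and none with the set as a block or without Bcl6yfp/+ replicate 1. With day as a covariate the cell cycle and cholesterol synthesis lists went the other way. Interferon-induced genes had a median of 0.19 (camera adjusted p = 1.1e-11, adjusted p = 0.13 with an estimated correlation; Ifit3 0.69, SE 0.51), Th17 genes 0.38 (8.3e-05, adjusted p = 0.13 with an estimated correlation) and cell cycle genes -0.21 (0.00058, adjusted p = 0.72 with an estimated correlation). The camera adjusted p was 0.0018 for genes reported to be repressed by BCL6, 0.0089 for CD8 T and NK markers, 0.0089 for naive and memory genes, 0.0097 for regulatory T cell genes, 0.018 for cholesterol synthesis genes, 0.021 for Th1 genes and 0.033 for TCR response genes (0.15 with the replicate block), adjusted p = 0.37, 0.13, 0.37, 0.13, 0.7, 0.37 and 0.37 with an estimated correlation. Tfh genes had 0.15. Co-stimulatory receptors (0.054) and myeloid markers (0.11) had 0.026 and 0.049 with the replicate block. In set 6, with 2 arrays of each genotype, the median was 0.01 for Tfh, 0.05 for cell cycle, 0.07 for interferon-induced and 0.10 for cholesterol synthesis genes.

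Day 10 cells were compared with day 7 cells across the YFP-positive (n = 4), YFP-negative (n = 4) and Bcl6+/+ (n = 3) groups. Gal, which encodes the neuropeptide galanin, rose 194-fold (log2 7.60, SE 1.07, adjusted p = 0.011), and the membrane protein gene Susd2 27.1-fold (4.76, SE 0.76, adjusted p = 0.017). Rad54b, a DNA repair gene, fell 9.98-fold (log2 -3.32, SE 0.64, adjusted p = 0.046). The value for Gal is pooled over groups that differ. The day effect was 10.93 in YFP-positive, 9.44 in YFP-negative and 1.09 in Bcl6+/+ cells, with an adjusted p of 5.79e-05 and 0.000104 for the difference of Bcl6+/+ from the first 2. YFP-positive cells have 1 day 10 array and Bcl6+/+ cells 1 day 7 array, so these p-values take their spread from other arrays. Other rises were Fam71b (4.71), Nrbp2 (3.88) and Abcc3 (3.76), and other falls the nuclear envelope gene Nrm (-2.15), Suv39h2 (-1.91), the ubiquitin enzyme gene Ube2t (-1.83) and Ece2 (-1.02). These 10 had adjusted p from 0.71 to 0.98 with the replicate block. In all 23 genes passed (18 higher, 5 lower, but 54 higher and 94 lower without 3 arrays of high 3' to 5' difference; 1011 at an unadjusted p under 0.05), and 0 with the replicate block or the set as a block. Without YFP-positive replicate 4, YFP-negative replicate 2 or YFP-negative replicate 4, 0 passed in limma, and without Bcl6+/+ replicate 3, 395 (130 higher, 265 lower).

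Cell cycle genes were lower at day 10 in 41 of 41 (median log2 -1.74, relative to a shift of all genes of -0.14, camera adjusted p = 9.3e-22, adjusted p = 0.42 with an estimated correlation). In limma 0 passed over all genes and 35 fell over the list alone, and the thymidine kinase gene Tk1 had -2.95 (SE 0.70, adjusted p = 0.092). The list mean was lower on every day 10 array only in the YFP-sorted groups: 9.62 at day 10 against 11.6 to 12.3 at day 7 in YFP-positive cells, and 8.03 and 6.98 against 9.99 and 10.3 in YFP-negative cells. In Bcl6+/+ cells it was 10.66 and 9.94 at day 10 against 10.13 at day 7. In the YFP-sorted groups day 10 also goes with Y-linked transcripts, so the 2 cannot be separated there. Cholesterol synthesis genes were lower in 13 of 13 (-0.59; 7.9e-05, adjusted p = 0.43 with an estimated correlation, and 0.0791 with the set as a block). Interferon-induced genes (median 0.09; 0.0056, adjusted p = 0.59 with an estimated correlation) and myeloid markers (0.84; 0.0056, adjusted p = 0.22 with an estimated correlation) were called higher, but not without YFP-negative replicate 1 (0.142 and 0.0504), whose mean over the myeloid markers was 8.69 against 6.51 to 7.12 on the other YFP-negative arrays. Bcl6 (0.17, SE 0.20), Cxcr5 (0.04, SE 0.25) and Pdcd1 (0.15, SE 0.26) did not pass.

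**Figure D4:**
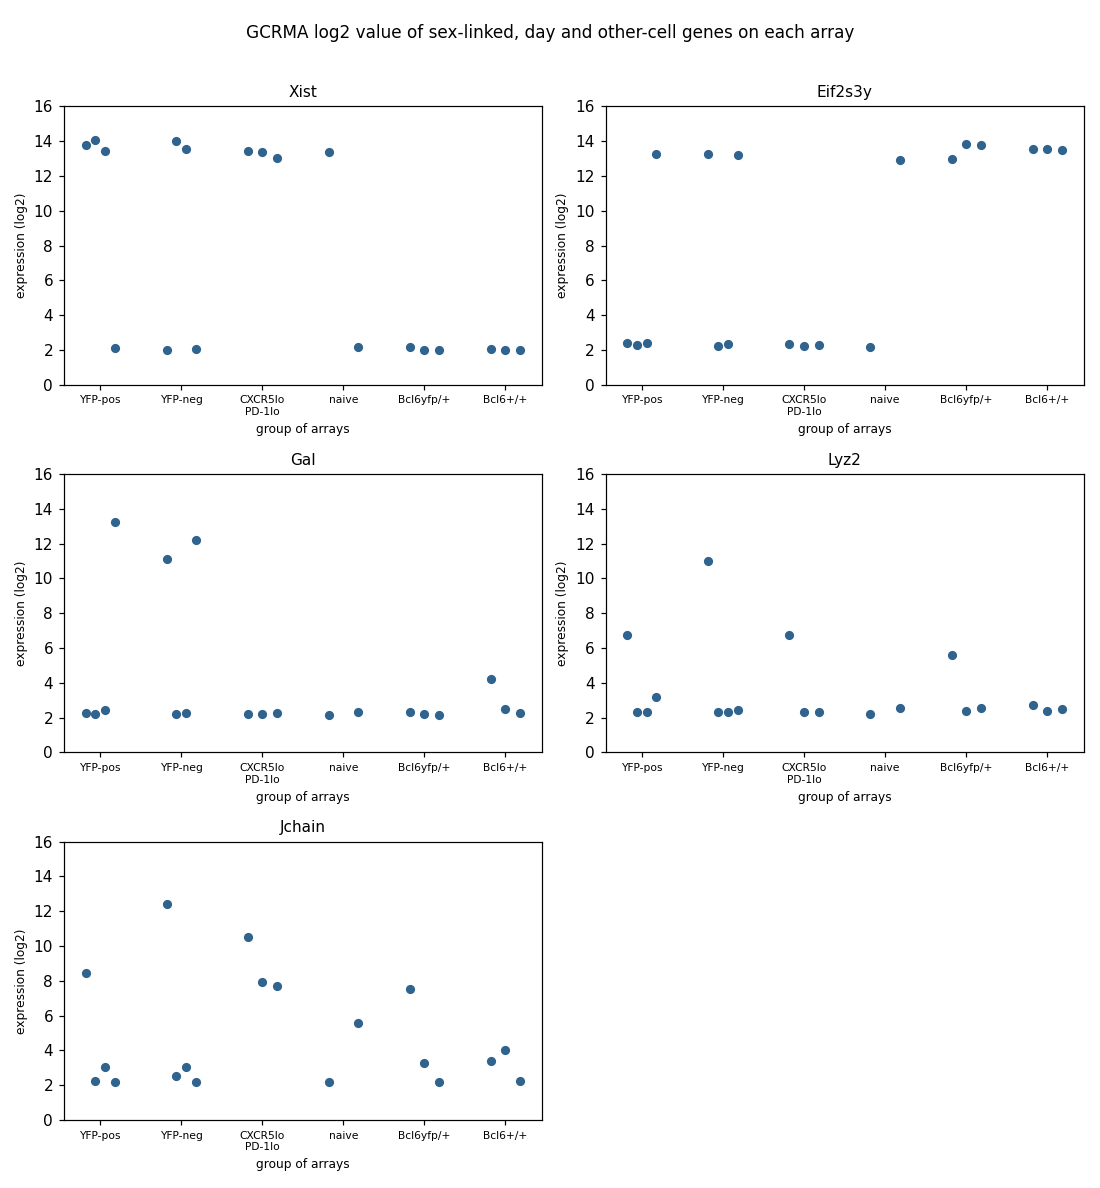
Level (log2, y axis) of Xist, Eif2s3y, Gal, Lyz2 and Jchain on each of the 19 arrays, arranged by group (x axis), 1 point per array with no error bars. Gal was 13.2 in YFP-positive replicate 4, and Lyz2 was 10.98 in YFP-negative replicate 1.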

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

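The tests of explanations for YFP-negative replicate 1, for the day effect and for CXCR5lo PD-1lo replicate 1, with their thresholds, were chosen only after the result was seen, and the counts over other splits of the arrays were planned. For some tests the rule for reading the value was also changed after values were seen. With a rule on the quartiles, which was tried and dropped, collection day alone and carry-over would both be undecided, so the quartiles are given below.

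YFP-negative replicate 1 had a mean of 10.1 over the germinal centre B and plasma cell markers, against 5.26 to 5.98 on the other YFP-negative arrays. All 5 abundant markers tested (Lyz2, S100a8, S100a9, Jchain and Ighm) stood at least 2 log2 units above every other YFP-negative array. For Ighm this held at its probe set with the widest range, while the one that represents the gene read 11.75 here and 11.65 to 11.69 on the others. RNA from myeloid and antibody-secreting cells could give this, although the sort on CXCR5, PD-1 and YFP should remove them. The 5 were chosen after the result was seen, so their number is no independent support. Of 19 myeloid genes 7 reached log2 4 here, against 3 on each other YFP-negative array, and Itgam (2.175), Csf1r (2.1), Cd14 (1.96) and Spi1 (2.05) stayed at the floor. Jchain was also 7.906 and 7.724 on CXCR5lo PD-1lo replicates 2 and 3. An effect shared by its normalization set is argued against for S100a8 and S100a9 alone, which exceeded the set's other arrays by at least 8.08 log2. Of Lyz2, Jchain and Ighm, 2 also stood out on both other arrays of the set (Lyz2 at 6.73 and 6.76 against 10.98 here, Jchain at 8.45 and 10.53 against 12.42). Ighm, at its probe set with the widest range, was 12.05 and 12.36 on them against 14.96 here. It was also 11.09 and 12.71 on CXCR5lo PD-1lo replicates 2 and 3. For Lyz2, Jchain and Ighm a shared effect stays open. A wrong label cannot be told apart: 89.5% of 534 genes put the array nearer to the YFP-negative than to the CXCR5lo PD-1lo arrays, but only 6 genes were available against YFP-positive, of which 66.7% did. The filter left out S100a8 (10.3) and S100a9 (12.1) on this array, which is 2 genes at log2 8 or more against 0 in naive cells, and no biological explanation was tested.

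The day effect differed from Bcl6+/+ cells in 14 genes for YFP-positive cells (478 at an unadjusted p under 0.05) and in 5 for YFP-negative cells (298), tested as interaction terms in limma, where YFP-positive cells have 1 day 10 array and Bcl6+/+ cells 1 day 7 array, so that other arrays supply the spread and an oddity of 1 array can pass for a difference. The 14 were Ada, Arid3b, Bard1, Cp, Esm1, Esyt1, Fam71b, Flrt2, Gal, Gfra4, Grk3, Hsf2bp, Runx3 and Tns1, the 5 were Ascl2, Esm1, Flrt2, Gal and Grk3, and all but Fam71b, Gal, Ascl2 and Runx3 are named only because of this result. Over the 23 day genes an effect of sex alike in all groups is argued against, as day 7 arrays with Y-linked transcripts had a median position of -0.00422 (upper quartile 0.186) between day 7 at 0 and day 10 at 1, and RNA from the cells seen in YFP-negative replicate 1 is argued against by 2 day 10 arrays with S100a9 and Jchain both under log2 4. Collection day alone gave a ratio of Bcl6+/+ to YFP-sorted effects of 0.196 (quartiles over genes 0.139 to 0.418). The median effects were 0.777 in Bcl6+/+ cells and 3.50 in YFP-negative cells. The standard errors of the single genes in Bcl6+/+ cells had a median of 0.623, which is not the error of 0.777. With the day 7 arrays of both Bcl6 genotypes as the reference in place of the 1 Bcl6+/+ array, the ratio was 0.212. These ratios argue against a like effect in all groups. Replicate, normalization set and genotype differ along with these groups and stay open, as do RNA from cells that S100a9 and Jchain do not mark and an effect of sex within the YFP-sorted groups, where every day 10 array and no day 7 array has Y-linked transcripts.

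CXCR5lo PD-1lo replicate 1 was nearer to the CXCR5hi PD-1hi arrays in cell cycle genes, with a median excess of 3.19 log2 over the other CXCR5lo PD-1lo arrays. Carry-over of CXCR5hi PD-1hi cells would need a share of 12.9% to give its Il21 level. To test this, 15 genes were chosen as abundant in YFP-positive cells and under the filter value on CXCR5lo PD-1lo replicates 2 and 3. They lay at a median of -2.91 log2 from the level that share needs (quartiles -4.21 to -0.77). Of them 11 lay at least 1 log2 below it, which argues against carry-over as the whole cause. The cell cycle gene Cenpe lay above it (8.164 against 6.95 needed), as did Rad51ap1 and Pif1. Not all 15 can therefore be taken as specific to CXCR5hi PD-1hi cells. With YFP-negative cells as the source the median was -3.63 over 9 genes. A cell cycle effect of the same size across the set is argued against, as YFP-positive replicate 1 had only 0.0981 of the excess (0.313 log2). Its list mean was 12.3, as on YFP-positive replicate 3, so a smaller effect at that high level could be missed. YFP-negative replicate 1, a day 10 array, cannot speak to it. Over all genes, deviations from the group means correlated at r = 0.684 between YFP-positive and CXCR5lo PD-1lo replicates 1. Other effects shared by the set therefore stay open. What made this array differ stays open.

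Among 88 groups of 4 arrays tested, 6 had 1 array apart from the other 3, where chance gives about 4.4. Besides the plasma cell markers, the mean over chemokine receptors and homing molecules was 8.85 in YFP-negative replicate 4 (others 9.59 to 9.70). The mean over interferon-induced genes was 9.70 in YFP-positive replicate 2 (others 9.80 to 9.81). YFP-positive replicate 4 had a mean of 9.43 over cholesterol synthesis genes (others 10.5 to 10.7), Acpp at 7.22 (6.66 to 6.76) and Pdcd1 at 14.7 (others 14.3 to 14.4). In data outside the comparisons, the Gapdh control probe sets differed by 2.34 log2 between the 3' and 5' ends in Bcl6+/+ replicate 1, against at most 1.26 in naive cells. In YFP-positive replicate 1, 1 gene left out by the filter reached log2 8 (Igk-V21, 8.94).

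Other splits of the arrays were tried. For YFP-positive and YFP-negative cells 3 of 35 splits gave as many genes as the real 12, so chance could not be excluded. The highest other gave 187 genes and set YFP-positive replicates 1, 2 and 3 with YFP-negative replicate 2 against the rest, close to the division by sex-linked genes and day. That points to a structure of the samples, but 6 of the 8 arrays keep their place in the sort, so its calls may come from the sort too, and no test separates the 2. Among the 8 splits that part every pair of the same number, the real one alone gave calls (highest other 0, and 0 against 74 with the replicate block). For YFP-positive over CXCR5lo PD-1lo cells (1049, highest other 373) and for YFP-negative over CXCR5lo PD-1lo cells (648, highest other 43), 1 of 35 splits gave as many, which argues against chance where pairing is ignored. Among the 8 splits that part every pair, the highest other with the replicate block was 1130 against 2068 and 453 against 1114. In all 3 comparisons 8 splits are too few to exclude chance with the pairing kept. For the Bcl6 genotypes 10 splits are too few (0, highest other 0). For the day effect 2 of 72 assignments gave as many as the real 23, but these ignore the pairing of arrays, and 0 genes passed with the replicate or set block, so chance is not excluded. The highest other, which keeps the labels of the YFP-sorted arrays and takes Bcl6+/+ replicates 2 and 3 as day 10, gave 420. That again points to a structure of the samples.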

How the results depend on the processing

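Fits with the normalization set as a block, with only 11 arrays, with replicate numbers 2 to 4, without 3 arrays of high 3' to 5' difference, without genes of chromosomes X and Y (day effect, 29 genes), of lists without YFP-negative, CXCR5lo PD-1lo or Bcl6yfp/+ replicate 1, and of lists or named genes with the replicate block were chosen only after the data were seen. The other alternatives were planned. Where a count or a direction changed, the cause was not tested. Between YFP-positive, YFP-negative and CXCR5lo PD-1lo cells the replicate and set blocks give the same fold changes, so their counts differ in the spread alone.

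For YFP-positive over YFP-negative cells 12 genes passed. The count was 7 with no filter on low values, 2 with only the arrays of the groups compared, 511 with arrayWeights (400 higher, 111 lower), 66 after quantile normalization, 20 with day 7 arrays only and 74 with the replicate block. It was 1541 with the normalization set as a block, 1686 with quantile normalization and the set as a block, 21 without the 3 arrays of high 3' to 5' difference, 268 with the replicate block and only 11 arrays, and 192 with the block and numbers 2 to 4 (153 higher, 39 lower). Leaving out each array gave 4 (without YFP-positive replicate 3) to 307 (265 higher, 42 lower, without YFP-positive replicate 4). Other runs gave 7 and 8 without YFP-positive replicates 1 and 2, and 6, 5, 10 and 8 without YFP-negative replicates 1 to 4. The direction of all 11 named genes was the same within each normalization set, which is fixed for genes named because their groups did not overlap.

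For YFP-positive over CXCR5lo PD-1lo cells 1049 genes passed, 1589 with all probe sets, 3084 with arrayWeights, 1953 after quantile normalization, 2068 with the replicate block, 4439 with the set as a block, 4594 with quantile normalization and the set, 1700 without the 3 arrays and 3689 with the block and only 11 arrays. Leaving out each array gave 654 (without CXCR5lo PD-1lo replicate 2) to 1051, and 683 without CXCR5lo PD-1lo replicate 3. For YFP-negative over CXCR5lo PD-1lo cells 648 passed, 1922 with arrayWeights, 1229 after quantile normalization, 411 with day 7 arrays only, 1114 with the replicate block, 3026 with the set as a block, 3151 with quantile normalization and the set, 1041 without the 3 arrays, 552 with only the arrays of the groups compared and 2386 with the replicate block and only 11 arrays. Leaving out each array gave 414 (without CXCR5lo PD-1lo replicate 2) to 605.

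Against naive cells the counts moved with the 2 naive arrays. YFP-positive over naive gave 2863, 5459 with all probe sets, 4490 with arrayWeights, 1588 with the extraction label as a block, 4663 with the set as a block and 4750 with quantile normalization and the set; leaving out arrays gave 1588 (without naive replicate 2) to 3186. YFP-negative over naive gave 2098, 4179 with all probe sets, 3207 with arrayWeights, 1124 with the extraction block, 4131 with the set and 4237 with quantile normalization and the set; leaving out arrays gave 1124 (without naive replicate 2) to 2108, and 1400 without naive replicate 1. CXCR5lo PD-1lo over naive gave 1185, 2377 with all probe sets, 416 with its own arrays, 3132 with arrayWeights, 574 with the extraction block, 696 with the same extraction, 2319 with the set and 2489 with quantile normalization and the set; leaving out arrays gave 574 (without naive replicate 2) to 1151, with 699 without naive replicate 1 and 655 without CXCR5lo PD-1lo replicate 1. Both genotypes over naive gave 3410, 6741 with all probe sets, 1879 with their own arrays, 6205 with arrayWeights, 1853 with the extraction block and 837 with the same extraction; leaving out arrays gave 1716 (without naive replicate 2) to 5257 (without Bcl6yfp/+ replicate 1), and 1853 without naive replicate 1. An extraction block leaves 1 naive array per label, which is why its counts equal those without a naive array.

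For the Bcl6 genotypes limma called 0 genes (287 at an unadjusted p under 0.05), 4 with the set as a block, 3 with quantile normalization and the set, 1 without the 3 arrays and 449 with arrayWeights, and 0 to 0 leaving out each array. For the day effect 23 passed, 1 with no filter, 55 with trend and robust options, 0 with its own arrays, 5454 with arrayWeights (849 higher, 4605 lower), 46 after quantile normalization, 0 with the replicate block, 0 with the set, 0 with quantile normalization and the set, and 148 without the 3 arrays (54 higher, 94 lower). Within single groups the count was 117 in YFP-positive cells, with 1 day 10 array, 48 in YFP-negative cells and 1 in Bcl6+/+ cells, with 1 day 7 array, so the first and the last rest on single arrays. Leaving out each array gave 0 (without YFP-positive replicate 4, YFP-negative replicate 2 or YFP-negative replicate 4) to 395 (130 higher, 265 lower, without Bcl6+/+ replicate 3), with 131 and 117 without Bcl6+/+ replicates 1 and 2, 52 and 8 without YFP-negative replicates 1 and 3, and 12 without YFP-positive replicate 2. In all 9 comparisons the weights from arrayWeights did not converge to tolerance, so its counts are uncertain.

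Other probe sets went the opposite way for Dcbld2 (-0.11, YFP-positive over YFP-negative), Pfkl (-0.30, YFP-positive over CXCR5lo PD-1lo), Tmem176a (-0.14, YFP-positive over naive), and Pfkp (-0.32) and Dtl (-0.23) in both genotypes over naive. Ighm had 2.50, 2.59, 1.80, 0.34, 2.49, 2.56 and 1.61 over naive in YFP-positive cells, 3.63, 3.55, 2.33, 0.16, 3.46, 3.75 and 2.88 in YFP-negative cells, and 3.62, 2.40, 0.90, 2.88, 4.61 and 0.70 in both genotypes. At the Ighm probe set with the widest range the YFP-positive and YFP-negative values rest on replicate 1. None of these opposite values passed the threshold; of 336 comparisons of a called gene with another probe set, 236 were the same, 75 weaker and 25 opposite.

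With the set as a block, Dnajb1 had -0.053 in both genotypes over naive, the Th1 list -0.029 and the regulatory T list -0.032 between the genotypes, and the naive and memory list 0.14 for the day effect. With day as a covariate the cell cycle list had -1.32 and the cholesterol list -0.57 between the genotypes, and the cell cycle list 0.75 in YFP-negative over CXCR5lo PD-1lo cells. Without CXCR5lo PD-1lo replicate 1 that list was called higher, at 0.83 (camera adjusted p = 0.00874, range over its alternatives 0.00441 to 0.986), so the call depends on 1 array and on the day adjustment, and without YFP-negative replicate 1 the list had 0.050. Between the genotypes 0 of the 10 called lists kept their call without Bcl6yfp/+ replicate 1, where the median was -0.091 for Th1, -0.064 for cell cycle, -0.27 for TCR response genes and -0.093 for CD8 T and NK markers. The fry test, which does not compare a list with other genes, had the opposite direction to camera between the genotypes for lists with medians of 0.025 (Th1), -0.21 (cell cycle), -0.076 (cholesterol), -0.16 (TCR response), -0.023 (naive and memory), 0.012 (regulatory T) and 0.0026 (BCL6-repressed). The same held for apoptosis (0.14), chemokine receptors (0.078) and cytokine receptors (-0.18) in both genotypes over naive, for chemokine (0.53) and cytokine receptors (0.073) in YFP-negative and for chemokine receptors (0.49) in YFP-positive cells over naive.

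Values that changed sign with no call on either side are not counted as opposite. Of 88 called list shifts, 11 held with an estimated correlation, 69 after quantile normalization, 67 with the set as a block and 81 with the mean of probe sets. Of 40 called shifts the replicate block kept 38, and it changed no other call than those given with the results. Without YFP-negative replicate 1 the helper lineage and oxidative phosphorylation lists between YFP-positive and YFP-negative cells had an adjusted p of 0.059 each. For the day effect interferon-induced genes (0.142) and myeloid markers (0.0504) lost their call without that array. Without CXCR5lo PD-1lo replicate 1 cytokine receptors in YFP-negative over CXCR5lo PD-1lo cells had 0.0736 and glycolysis in CXCR5lo PD-1lo over naive cells 0.0948. Of 421 called named genes 397 kept their call after quantile normalization, 380 with the set as a block and 419 with arrayWeights, and of 2806 runs without 1 array 2445 kept the call and 361 lost it, with none reversed. Of 177 named genes not called, 10 gained a call after quantile normalization, 39 with the set as a block and 68 with arrayWeights. The replicate block gave a call to 6 of 165. Genes near the floor of the GCRMA scale set the limit on fold changes.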

Other observations

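The tests of an intermediate position of YFP-negative cells were chosen only after the result was seen, and the rule for reading them was changed from medians to medians with quartiles after the values were seen. With medians only, the position over all chosen genes would have argued against an intermediate place and the position over naive and memory genes would have been read as intermediate.

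A hypothesis was that YFP-negative cells lie between CXCR5lo PD-1lo cells (position 0) and YFP-positive cells (position 1). Genes were chosen on replicates 1 and 2 and the position was measured in replicate 3, so 1 array was tested. Over 383 genes the median position was 0.824 (quartiles 0.584 to 0.998), which leaves open whether YFP-negative cells are intermediate or like YFP-positive cells. Over 7 naive and memory genes it was 0.645 (quartiles 0.472 to 0.864), with S1pr1 at 0.235, Klf2 at 0.374, Bach2 at 0.57, Ccr7 at 0.645, Il7r at 0.726, Igfbp4 at 1 and Dapl1 at 1.13. With 1 array and quartiles that reach both readings, neither can be excluded, although S1pr1 and Klf2 may lie nearer to the CXCR5lo PD-1lo level than the 0.824 of the wider set.

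The arrays also divide by sex-linked transcripts. Xist was high with Eif2s3y near the floor in YFP-positive replicates 1, 2 and 3, YFP-negative replicates 2 and 3, all CXCR5lo PD-1lo arrays and naive replicate 1. Eif2s3y was high with Xist near the floor on the other arrays, which include all Bcl6yfp/+ and Bcl6+/+ arrays. The labels do not give the sex of the mice.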
